A study of Homo sapiens with 3 samples.

How the data were processed

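RNA sequencing libraries from 3 cultures of HGC-27, an established human cell line from an undifferentiated gastric carcinoma, were compared. Per the labels, 1 culture received a control siRNA, 1 an siRNA against IRF3 and 1 an siRNA against YAP, each for 48 h at passage 6. Total RNA was extracted with TRIzol and libraries followed standard Illumina protocols, per the labels' protocols. The siRNA sequences, the library's strand setting, the gene counter and the annotation release are not given in the sources used here.

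The deposited table holds 1 FPKM column and 1 column of raw counts per library for 50868 genes, per the file headers. Alignment used TopHat2 version 2.0.9 on genome build hg38, per the submitters' processing notes. The deposited FPKM values were checked against the deposited counts. With each gene's length taken from its library of highest count, 100% of the 45223 nonzero values of the remaining libraries were within 1% of the count scaled by gene length and by the column total, as FPKM is defined. That gene length is the authors' and is not listed in the file. All value columns belong to these 3 libraries.

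Before the data were examined, the design assumed a table of FPKM values, and FPKM stayed the main unit although counts were present too. The log2 ratio of each gene was computed from FPKM plus a pseudocount of 1, which understates the change of low genes. Genes with a mean FPKM of at least 1 over the 3 libraries were kept, which left 11103 genes. A gene was called higher or lower when its ratio was at least 2-fold on this scale. With 1 library per group there is no replicate check, no test across samples and no p-value: the size rule describes these libraries. Ratios of counts carry a 95% interval from the exact (Clopper-Pearson) binomial interval of the count shared between a pair of libraries. PCR copies are not independent molecules, so these intervals cover counting error only.

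Likewise 27 gene lists were fixed in advance. For each list with at least 5 measured members, the median log2 ratio was placed as a percentile among 10000 random lists of the same size, drawn within 10 strata of mean FPKM. The central 95% of random medians runs from percentile 2.5 to 97.5. In a form added after seeing the data, the random lists were also matched on exon length and GC content, with 5 strata of level and 3 each of length and GC content. Both percentiles describe these libraries only.

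Genes were named by a rule fixed in advance. In each knockdown against control, it took the 10 largest increases and the 10 largest decreases among genes with a mean FPKM of at least 5, leaving out small RNAs and clone-based symbols. For both knockdowns together and for the direct comparison it took 5 genes in each direction. From each list it took up to 4 members with the largest ratio in either direction, and IRF3 and YAP1 always. CTGF, CYR61 and the few other genes named outside this rule are marked where they appear. A few genes that the rule takes are not reported here.

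The comparisons of both knockdowns share 1 control library, which cannot be split. The overlap and correlation were therefore set beside 100 simulated sets of 3 unchanged libraries, with Poisson noise alone and with an assumed coefficient of variation between libraries of 0.1 or 0.2. Intervals of correlations and covariances come from 1000 resamplings of genes, which are not replicates.

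Gene class, union exon length, GC content and exon overlap came from GENCODE release 29 on the same build. Of the kept genes, 10426 (93.9%) had identical coordinates there, and 11066 had a length and a GC content. Coordinates are printed as deposited.

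Other settings fixed before the data were examined were a pseudocount of 0.1, a filter of 5 FPKM, no filter, centring on the median gene, a 3-fold threshold, protein-coding genes only, and the deposited counts as TMM-scaled CPM from edgeR. Added after seeing the data were removal of an additive spline trend (4 degrees of freedom each for level, exon length and GC content) and summing of counts over genes with overlapping exons. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, patsy 1.0.2, R 4.3.3 and edgeR 4.0.16.

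The calling rule was tested on simulated counts for the YAP siRNA against control comparison, with 200 genes changed and 11051 genes passing the filter. It called 48 of 50 genes raised 3-fold, 36 of 48 lowered to 0.333 of their level, none of those changed 1.5-fold, and 5 of 10857 unchanged genes. These counts held Poisson noise alone, so the rule was not tested there against variation between cultures. With an assumed variation of 0.2 between libraries, unchanged libraries gave 84.2 calls in this comparison on average.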

Results

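Gene expression was measured by RNA sequencing in HGC-27 gastric cancer cells 48 h after transfection with a control siRNA, an siRNA against IRF3, a transcription factor of the antiviral interferon response, or an siRNA against YAP, the transcriptional coactivator restrained by the Hippo pathway. Each condition had 1 library, so no difference below has a replicate check. Counts assigned to genes came to 13949401 in the control, 14941556 in the IRF3 siRNA and 14385959 in the YAP siRNA library. At least 1 FPKM was reached by 11498, 10854 and 10899 genes in that order.

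The targeted genes were read first. YAP1 (ENSG00000137693, chromosome 11, 102110461 to 102233423, hg38) stood at 5.89 FPKM in the control, 3.58 with IRF3 siRNA and 2.23 with YAP siRNA, from 861, 561 and 337 counts. It fell by 1.09 on the log2 scale in the YAP siRNA library, where the count ratio to control was 0.380 (counting interval 0.334 to 0.431). With the trend in level, length and GC content removed, its log2 ratio there was -0.90, short of 2-fold. In the IRF3 siRNA library YAP1 had a log2 ratio of -0.59 and a count ratio of 0.608 (0.546 to 0.677). IRF3 (ENSG00000126456, chromosome 19, 49659569 to 49665875) stood at 3.55, 2.90 and 3.86 FPKM, from 681, 597 and 764 counts. Its log2 ratio with IRF3 siRNA was -0.22, a count ratio of 0.818 (0.732 to 0.915), short of the 2-fold rule. IRF3 shares exon sequence with BCL2L12 on the opposite strand, and the strand setting of the counts is not given. With both genes' counts summed, the log2 ratio with IRF3 siRNA was -0.02, so IRF3 checks that library's label only weakly.

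**Figure D1:**
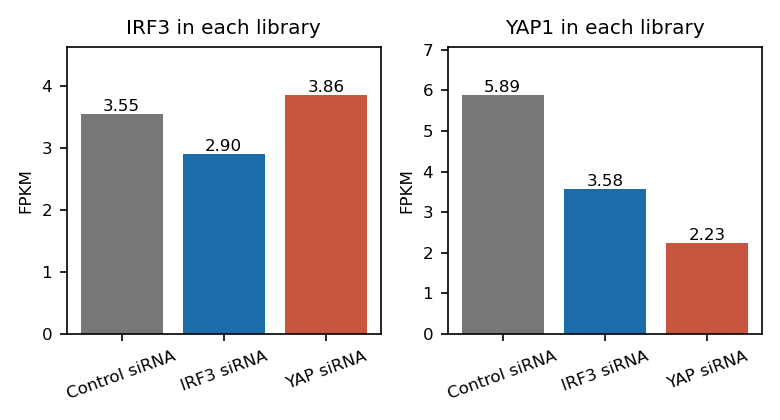
Deposited FPKM (y axis, from 0) of IRF3 and YAP1 in each of the 3 libraries, 1 bar per library. IRF3 was lowest with IRF3 siRNA at 2.90, and YAP1 was lowest with YAP siRNA at 2.23.

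The comparison of YAP siRNA with control asked which transcripts differed after YAP knockdown. PTTG1IP (ENSG00000183255, chromosome 21, 44849585 to 44873903), which encodes a binding partner of securin, fell by 1.82 on the log2 scale, from 35.6 to 9.36 FPKM. AHNAK, a giant scaffold protein, fell by 1.53, and SLC16A1, a monocarboxylate transporter, fell by 1.42. PRKDC, the catalytic subunit of DNA-dependent protein kinase, fell by 1.39. FAM168A, GPR157, FAT1 (an atypical cadherin) and CNOT1 (the scaffold of the main deadenylase complex) fell by 1.31, 1.25, 1.20 and 1.10. IER2, an immediate early gene, rose from 7.01 to 24.5 FPKM (log2 ratio 1.67, count ratio 3.49, counting interval 3.19 to 3.82). The histone gene H3F3B rose by 1.37 (1.10 with overlapping genes summed), the long noncoding RNA DANCR by 1.26, the junction protein gene F11R by 1.18, NUDCD3 by 1.16, the polyubiquitin gene UBB by 1.10 (0.92 with the trend removed), CYB5R3 by 1.09 and FAM220A by 1.08.

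In total 39 genes were higher and 52 lower with YAP siRNA among 11103. Of these 91 genes, 65 (71.4%) were protein-coding and 50 (54.9%) shared exon sequence with another counted gene, beside 84.8% and 42.3% of all genes kept. TEN1 (log2 ratio 1.29) and MRPS16 (1.27) were such genes, and their summed clusters gave -0.06 and 0.90. So was 1 of the entries for RABL6 (-1.05, summed 0.27). FTH1P10 (-3.64, with 4 counts in the YAP siRNA library) kept its value when summed and is uncertain as a ferritin pseudogene with near-identical copies. With TMM-scaled CPM the split was 78 higher and 350 lower, and with a pseudocount of 0.1 it was 106 and 240. The excess of decreases was absent with the 5 FPKM filter (18 and 18) and at 3-fold (9 and 8), and the split was 33 and 35 with the trend in level, length and GC content removed.

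With IRF3 siRNA, TGOLN2 (ENSG00000152291, chromosome 2, 85318020 to 85328425), a membrane protein of the trans-Golgi network, fell by 2.25, from 9.80 to 1.27 FPKM. The splicing factor gene SRRM2 fell by 1.73 (-1.05 with overlapping genes summed), AHNAK by 1.62, C9orf69 by 1.51 and SURF4, a cargo receptor of the early secretory pathway, by 1.47. LIPA, the lysosomal acid lipase, fell by 1.30, the actin-binding coronin CORO1C by 1.26 and PRKDC by 1.25. H3F3B rose by 1.36 (count ratio 2.72, counting interval 2.57 to 2.88), NUDCD3 by 1.24, TMEM164 by 1.12, CYB5R3 by 1.08, the nucleoredoxin gene NXN by 1.06, C21orf33 by 1.05 and TRIM16L by 1.04. SLC35A4 completed the 10 largest increases at 0.99, under the 2-fold rule.

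The IRF3 siRNA library had 43 genes higher and 68 lower than control. Of these 111, 76 (68.5%) were protein-coding and 61 (55.0%) shared exon sequence with another counted gene. The readthrough gene HNRNPUL2-BSCL2 (log2 ratio -1.17) gave -0.25 with its cluster summed. The nuclear copies of mitochondrial sequence MTATP6P1 (5.94) and MTATP8P1 (-5.37) overlap on chromosome 1 and moved in opposite directions, and their summed cluster gave 3.66. TMM-scaled CPM gave 84 higher and 418 lower, a pseudocount of 0.1 gave 96 and 284, and the 5 FPKM filter gave 11 and 30. The excess of decreases was absent with the trend removed (41 and 40) and at 3-fold (13 and 12).

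The direct comparison, which leaves out the control library, had 33 genes higher and 35 lower with IRF3 siRNA than with YAP siRNA. Among them TGOLN2 (-1.78), IER2 (-1.68), SURF4 (-1.47) and C9orf69 (-1.40) were lower with IRF3 siRNA, and PTTG1IP (1.79) was higher. MTATP8P1 (-5.21), MTATP6P1 (5.72), FTH1P10 (3.79), RABL6 (3.12) and TOMM6 (1.61) completed the named genes and each has an overlapping or near-identical partner. Summed over overlapping genes, RABL6 gave -0.19 and TOMM6 -0.03, while the cluster of MTATP8P1 and MTATP6P1 gave 3.74. By such sums, 9 were higher and 16 lower. The YAP1 log2 ratio in this comparison was 0.50.

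Both knockdowns shared 15 genes that were higher and 26 that were lower than control. AHNAK (-1.62 with IRF3 siRNA, -1.53 with YAP siRNA), PRKDC (-1.25, -1.39), FAM168A (-1.16, -1.31), FAT1 (-1.15, -1.20) and CNOT1 (-1.08, -1.10) led the shared decreases. H3F3B (1.36, 1.37), NUDCD3 (1.24, 1.16), CYB5R3 (1.08, 1.09) and TMEM164 (1.12, 1.07) led the shared increases, followed by NXN (1.06, 0.99), which was under 2-fold with YAP siRNA. TMM-scaled CPM gave 39 shared increases and 193 shared decreases, while with the trend removed there were 17 and 12. With it removed, FAT1 (-0.80, -0.88) and CNOT1 (-0.78, -0.83) no longer passed 2-fold in either knockdown, nor did PRKDC (-0.92) and CYB5R3 (0.97) with IRF3 siRNA.

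Across genes the log2 ratios of both knockdowns had a Pearson r of 0.715 (0.678 to 0.749 over resampled genes) and a Spearman rho of 0.780, and 80.8% of genes had the same sign. Genes are not independent replicates. Unchanged libraries simulated against 1 control gave r of 0.512, 67.1% of genes with the same sign and 2.32 shared calls with Poisson noise alone. Independent lists of these sizes would share 0.151 increases and 0.319 decreases. The covariance was 0.0769, beside 0.0083 simulated with Poisson noise, 0.0219 with an assumed variation of 0.1 between libraries and 0.0631 with 0.2. The last setting gave r of 0.502, 10.7 shared calls and a variance of 0.125 in the direct comparison, where 0.0619 was observed. It also gave 83.8 calls with IRF3 siRNA, 84.2 with YAP siRNA and 82.5 in the direct comparison, where 111, 91 and 68 were observed. Were the 3 libraries to vary independently, their own variances would be 0.0769 for the control, 0.0387 for IRF3 siRNA and 0.0232 for YAP siRNA. The simulations gave all 3 equal variation, so none held a more deviant control. The excess may come in part or in whole from the shared control library, or from an effect of both knockdowns.

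**Figure D2:**
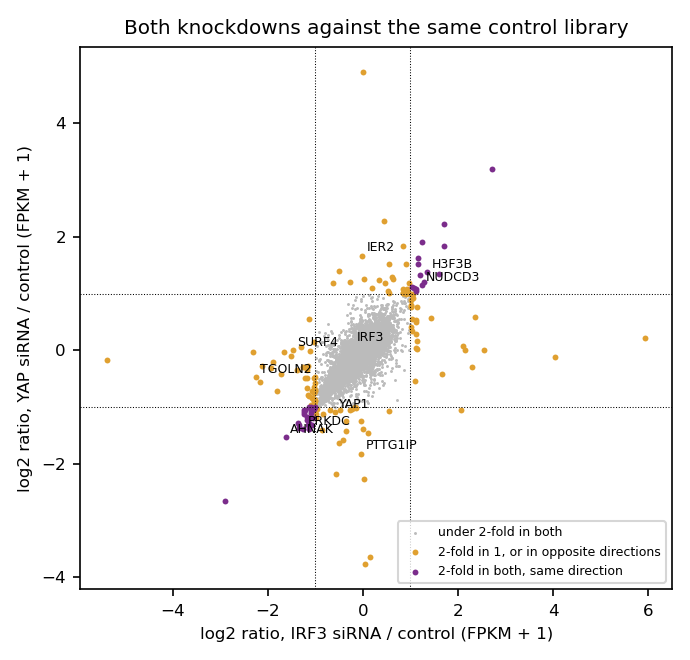
Each point is 1 of 11103 genes, with its log2 ratio to control for IRF3 siRNA (x axis) and YAP siRNA (y axis) on FPKM plus 1. Dotted lines mark 2-fold, and the 41 genes past it in the same direction in both knockdowns are purple.

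The lists closest to the targeted proteins came next, with YAP siRNA given first in each pair of values. Of 15 measured YAP/TEAD target genes, 13 had ratios below 0 in each knockdown, and the medians were -0.21 with YAP siRNA (percentile 3.84 of random lists) and -0.18 with IRF3 siRNA (11.9), both inside the central range. On the FPKM plus 1 scale PTPN14, a phosphatase that binds YAP, was the single member past 2-fold (-1.06 and -1.22). It no longer passed with the trend removed (-0.70 and -0.83). TGFB2 (-0.55 and -0.80), ASAP1 (-0.60 and -0.72) and MYOF (-0.52 and -0.61) were under 2-fold on that scale. Their control levels were 2.3, 2.3 and 2.5 FPKM, where the pseudocount shrinks ratios. Their count ratios to control were 0.54 and 0.39, 0.52 and 0.44, and 0.57 and 0.51 in that order. CYR61 (-0.07 and 0.11) and CTGF (-0.21 and -0.06), named after their values were seen as the most used YAP target genes, did not pass 2-fold on that scale. The control level of CTGF was below those of TGFB2, ASAP1 and MYOF, so the pseudocount shrinks its ratios more. Failing the 2-fold rule therefore says little about CTGF. The Hippo components had medians of -0.19 with YAP siRNA (percentile 2.13) and -0.30 with IRF3 siRNA (0.09). The former lay inside the central range (17.4) when random lists were also matched on length and GC content, and both did with the 5 FPKM filter. Among the members were AMOT at -0.86 and -0.77, STRN at -0.94 and -0.67, and WWC2 at -0.80 and -0.84.

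In this and the following lists IRF3 siRNA is given first. Interferon-stimulated genes had 19 of 52 members measured, none past 2-fold, and medians of 0.01 with IRF3 siRNA (percentile 52.2) and 0.04 with YAP siRNA (68.0). IFITM1 (0.95 and 0.91), UBE2L6 (0.88 and 0.84), EIF2AK2 (-0.68 and -0.47) and IFI35 (0.48 and 0.20) had the largest ratios, but IFITM1 shares exon sequence and its summed cluster gave 0.53 and 0.46. The nucleic acid sensing genes (10 measured, medians 0.02 and 0.06; IKBKE 0.29 and 0.39, MAVS -0.28 and -0.32) lay inside the central range of random lists. So did the NF-kB targets (7 measured, medians 0.11 and -0.06, the latter above 0 with TMM-scaled CPM; CCL2 -0.18 and -0.29).

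Extracellular matrix genes lay below all 10000 random lists in both knockdowns, with medians of -0.25 (IRF3 siRNA) and -0.19 (YAP siRNA) and 23 of 28 ratios below 0 in each. COL12A1 fell by 1.12 with YAP siRNA, which became -0.78 with the trend removed, and had -0.84 with IRF3 siRNA, and POSTN (-0.73 and -0.47), LAMC1 (-0.72 and -0.53) and FSTL1 (-0.35 and -0.74) were under 2-fold. Mesenchymal genes had medians of -0.21 and -0.14 (percentiles 0.20 and 0.75), with PDGFRA at -0.55 in both and FN1 at -0.53 and -0.34, against TWIST1 at 0.61 and 0.77. The first median lay inside the central range with the 5 FPKM filter, and the second (2.98) with length and GC content matched too. The growth factor and receptor list had medians of -0.25 and -0.27 (percentiles 1.11 and 0.32), with HES1 at -0.77 and -0.49 and JAG1 at -0.34 and -0.56, and lay inside that range in both knockdowns with the 5 FPKM filter. Actin and SRF target genes had medians of -0.02 and -0.08 (percentiles 12.2 and 1.11), and CORO1C was the single member past 2-fold, with IRF3 siRNA. Both medians changed sign with TMM-scaled CPM. That scaling raised the median gene by 0.09 and 0.08, so list medians close to 0 can turn without a change particular to the list.

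Mitotic genes had medians of -0.13 with IRF3 siRNA (percentile 0.26) and -0.15 with YAP siRNA (0.01), of which the first lay inside the central range (7.85) with length and GC content matched too. MKI67 fell by 1.12 with YAP siRNA, which became -0.81 with the trend removed, and had -0.99 with IRF3 siRNA. ANLN (-0.9998 and -0.91), TOP2A (-0.99 and -0.93) and CENPF (-0.74 and -0.88) did not reach the threshold on the FPKM plus 1 scale. Their count ratios to control were 0.42 and 0.46, 0.48 and 0.51, and 0.42 and 0.33 in that order. Replication genes had medians of 0.08 and 0.07 (percentiles 86.9 and 86.1), with CCND1 at -0.76 and -0.71 and E2F1 at 0.50 and 0.51. MYC-dependent growth genes had 0.21 with IRF3 siRNA (percentile 99.8) and 0.08 with YAP siRNA (82.4), while MYC itself had -0.11 and -0.95. Direct comparison placed this list above all random lists, with a median of 0.13. For p53 targets the medians were -0.03 and -0.01, both above 0 with TMM-scaled CPM (TP53INP1 -0.95 and -0.92), and for BCL2-family and apoptosis-inhibitor genes 0.04 and 0.12 (percentiles 83.8 and 99.1; MCL1 0.44 and 0.46).

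Nuclear genes of the respiratory chain had medians of 0.23 in both knockdowns (percentiles 99.8 with IRF3 siRNA and 99.97 with YAP siRNA), and 27 and 30 of the 32 ratios were above 0. NDUFB9 had 0.23 and 0.79, and COX4I1 had -0.65 and 0.30. Of 13 genes of the mitochondrial genome 5 were below 1 FPKM, 2 of them without counts, and how reads with several matches were counted is not given in the sources used here. The 8 measured genes lay below all random lists, with medians of -0.32 and -0.50 (MT-ND5 -0.68 and -0.76, MT-ND6 -0.66 and -0.64). With IRF3 siRNA 6 of them were below 0 and 2 above, and with YAP siRNA all 8 were below. In the direct comparison this list lay above the central range, with a median of 0.16 (percentile 99.7). Ribosomal protein genes had 0.19 and 0.18 (percentiles 96.2 and 98.1), with 60 and 70 of 72 above 0 and RPLP1 at -0.74 and 0.26. Stress response genes had -0.09 and -0.03 (percentiles 0.42 and 2.49; CHAC1 -0.14 and -0.96), and their signs turned with TMM-scaled CPM. Cholesterol synthesis genes had -0.09 and -0.06 (percentiles 1.79 and 3.43), and both also changed sign under that scaling. Heat shock and oxidative stress genes (0.03 and 0.04) and hypoxia and glycolysis genes (0.10 and 0.13; P4HA1 -0.87 and -0.46) lay inside the central range.

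**Figure D3:**
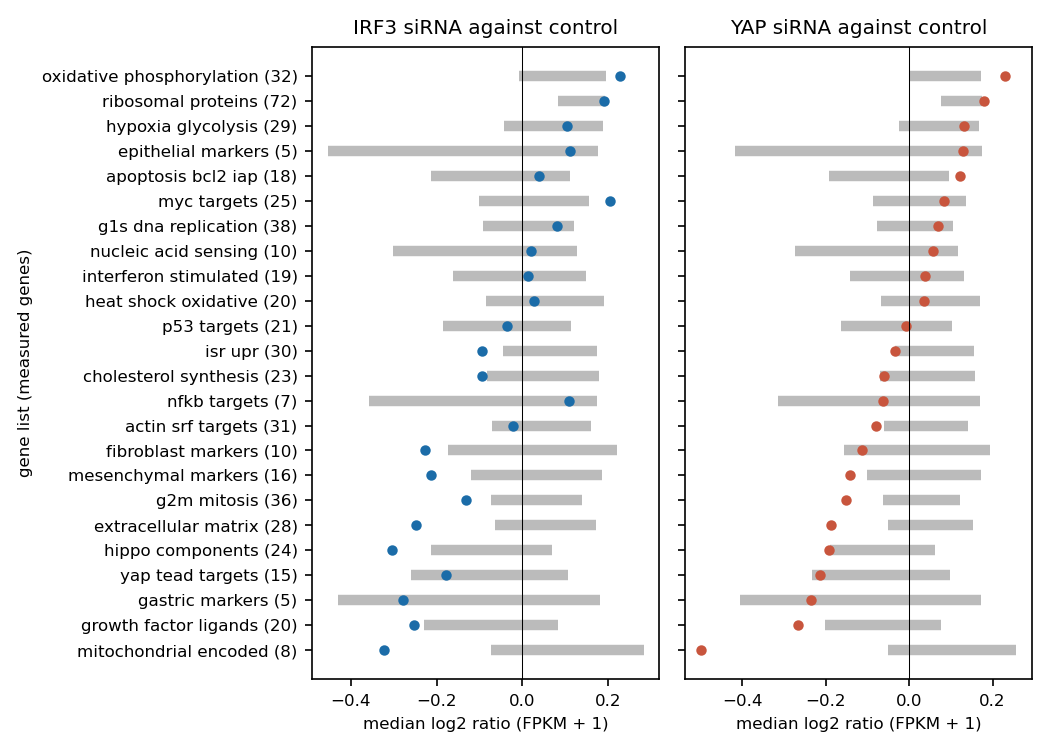
Median log2 ratio (x axis) of each fixed list with at least 5 measured genes, in each knockdown against control; grey bars hold the central 95% of 10000 random lists of matched expression. Extracellular matrix genes lie left of the bar at -0.25 and -0.19, and respiratory chain genes right of it at 0.23 in both.

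Markers of cell lineage and of other cell types were followed as well. Fibroblast genes had 10 of 15 members measured, with medians of -0.23 and -0.11 (percentiles 0.87 and 5.54; LUM -0.46 and -0.11, THY1 0.95 and 0.30). Epithelial genes had 5 of 30 members measured (medians 0.11 and 0.13; DSP -0.81 and -0.81) and gastric lineage genes 5 of 26 (-0.28 and -0.24; KLF5 -0.49 and -0.41). Of the leukocyte genes, CORO1A had -0.03 and 0.07. Haemoglobin and serum genes had 2 measured members (HBA1 0.45 and 0.12, HBB -0.04 and -0.19) and endothelial genes 1 (EGFL7 0.39 and 0.24).

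Ratios to control also followed properties of the genes. With genes divided into 10 equal groups, the group with the longest exon sequence had medians of -0.24 with IRF3 siRNA and -0.21 with YAP siRNA, and the group of lowest GC content had -0.21 and -0.17. The group of highest expression had 0.15 and 0.14. Level, length and GC content together accounted for 23.3% and 19.0% of the variance, and for 3.33% in the direct comparison. The direct comparison still followed GC content, with a Spearman rho across genes of 0.27, beside 0.41 for IRF3 siRNA and 0.28 for YAP siRNA against control. Of 24 lists, 9 lay below and 2 above the central range with IRF3 siRNA, and 6 and 2 of these also did when random lists were matched on length and GC content. With YAP siRNA these numbers were 8 and 3, and 4 and 3. Some lists share members, such as POSTN and COL1A1 (matrix and fibroblast) or FN1 and SPARC (matrix and mesenchymal), so these are not separate findings. The lists no longer outside were the mitotic, fibroblast and cholesterol lists with IRF3 siRNA, and the Hippo, actin, mesenchymal and stress response lists with YAP siRNA. With the 5 FPKM filter, the Hippo and growth factor lists in both knockdowns, the mitotic, mesenchymal and cholesterol lists with IRF3 siRNA and the ribosomal list with YAP siRNA no longer lay outside.

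**Figure D4:**
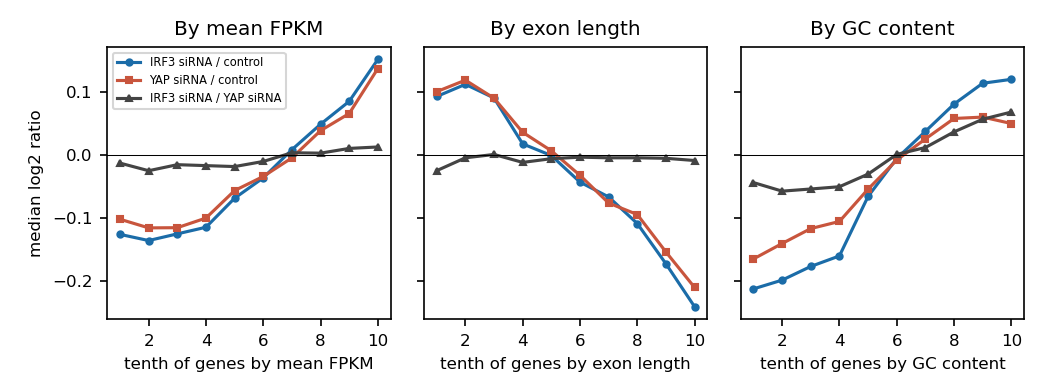
Median log2 ratio (y axis) in 10 equal groups of genes ordered by mean FPKM, union exon length or GC content (x axis, 1 lowest), for each knockdown against control and for the direct comparison. Both comparisons with control run from about 0.1 for short genes to -0.24 and -0.21 for the longest, while the direct comparison stays at -0.01 in the longest. By GC content the direct comparison has -0.04 in the lowest group and 0.07 in the highest.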

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

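The test of summed overlapping genes over all calls was set out before its result was seen; its parts and the tests of the shared direction and of YAP1 were chosen afterwards.

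RABL6 (ENSG00000282955) was the single gene past 2-fold in opposite directions, with log2 ratios of 2.07 with IRF3 siRNA and -1.05 with YAP siRNA; the difference was not tested. The table carries RABL6 under another identifier too (ENSG00000196642), at the same place on chromosome 9, and its counts ran the other way: 307, 1489 and 137 in the control, IRF3 siRNA and YAP siRNA libraries for the first, 2179, 1096 and 2888 for the second. Besides RABL6, 118 calls were made in 1 knockdown only. The other library need not be unchanged in such a call: F11R was just under 2-fold there (0.96 with IRF3 siRNA, 1.18 with YAP siRNA), while PTTG1IP was near 0 (-0.03 and -1.82). How many of the 118 lay close to the cut was not counted. By definition, division of reads between overlapping genes does not apply to the 53 that overlap no counted gene, so nothing was tested there. As the cause of every one of the other 65 it is argued against. Of these 65, 13 (exact interval of the share 11.1 to 31.8%) passed 2-fold with counts summed over overlapping genes and had a summed count ratio whose interval lay beyond 2-fold. The 13 include MTATP6P1 and FTH1P10, whose similar sequences elsewhere in the genome were not summed. On summing 51 (43.2% of all, 34.1 to 52.7, and 78.5% of the 65, 66.5 to 87.7) no longer passed. Yet summing also dilutes a real change and ended 72.7% (IRF3 siRNA) and 77.3% (YAP siRNA) of the 22 overlapping calls made in both knockdowns. Divided reads and a real change, in 1 library or in both, therefore cannot be told apart for the remaining 52. For RABL6 both entries moved in opposite directions in each knockdown (2.07 and -1.05, against -0.93 and 0.33), as divided reads would give. The sums over 9 joined genes gave 0.08 and 0.27, so the locus as a whole stayed under 2-fold. Divided reads may therefore be the cause there, which was not tested further.

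Both knockdown libraries differed from the control in the same direction. Counting noise in the shared control is argued against, since the covariance among the 3075 genes with a mean count of at least 1000 was 0.0683 (0.0631 to 0.0745 over resampled genes), beside a counting variance of 0.0012. A trend in level, length and GC content of the additive form fitted is argued against as the whole cause. After its removal 0.0480 (0.0437 to 0.0525) was left in these genes. A trend of another form was not tested and could leave such a remainder. A deviation of the control culture or library cannot be told apart from an effect shared by both knockdowns: both ratios use the same 1 control library, and either would give the covariance observed (0.0769 over all genes).

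YAP1 was also lower in the IRF3 siRNA library, with a log2 ratio of -0.59. An exchange of both knockdown libraries is argued against by YAP1 itself, whose count ratio of YAP siRNA to IRF3 siRNA was 0.624 (0.543 to 0.715), and more weakly by IRF3, at 0.752 (0.675 to 0.839) the other way. Summed with BCL2L12, which shares exon sequence with it, the log2 ratio of IRF3 in the direct comparison shrank from -0.32 to -0.17. The YAP1 value with IRF3 siRNA may lie within the ordinary spread of genes, as 6.66% of the 1111 genes in the same of 10 groups by expression had a ratio as low. With the trend removed it was -0.34, within the residual SD of all genes of 0.296 times 2, so a trend stays open. An effect of IRF3 knockdown on YAP1 also stays open, untested without replicates.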

How the results depend on the processing

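With 1 library per group no replicate could be left out, and depth limits each ratio only through counting error. No paired analysis was possible because each group has 1 library. Removal of the trend, summing of overlapping genes and matching on length and GC content were chosen after seeing the data. Counts are given as YAP siRNA, IRF3 siRNA, direct comparison and shared, against 91, 111, 68 and 41. A pseudocount of 0.1 gave 346, 380, 163 and 176 (r 0.677), since it shrinks low genes less. The 5 FPKM filter gave 36, 41, 27 and 14 (r 0.673) on 5291 genes, and the 3-fold threshold gave 17, 25, 31 and 4. TMM-scaled CPM, also with 1 added, gave 428, 502, 128 and 232 (r 0.755) on 14760 genes. It raised the median gene by 0.09 with IRF3 siRNA and 0.08 with YAP siRNA, yet called more decreases. An added 1 shrinks long genes less in CPM than in FPKM. The pseudocount of 0.1 on FPKM also called more decreases (96 higher and 284 lower with IRF3 siRNA, 106 and 240 with YAP siRNA). The cause was not tested. Summed overlapping genes gave 52, 64, 25 and 24 (r 0.789). Protein-coding genes alone gave 39 in the direct comparison and r of 0.784, on fewer genes. Trend removal gave r of 0.654 and kept the counts within 1.5 times, as did no filter and centring, but turned the shared split to 17 higher and 12 lower. YAP1 with YAP siRNA was -1.36 with a pseudocount of 0.1 and -0.90 with the trend removed; with IRF3 siRNA it was -0.34 with the trend removed.

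Among list medians outside the random range, the sign changed with TMM-scaled CPM for actin and SRF targets with YAP siRNA (0.00639), stress response genes with IRF3 siRNA (0.00574) and YAP siRNA (0.0543), and cholesterol synthesis with IRF3 siRNA (0.00628). TMM scaling raised the median gene by 0.0883 with IRF3 siRNA and 0.0812 with YAP siRNA. A median this close to 0 can therefore change sign without a change of its place among random lists. Medians inside the range that changed sign were those of p53 targets in both knockdowns, actin and SRF targets with IRF3 siRNA, NF-kB targets and cholesterol synthesis with YAP siRNA, and the Hippo and actin lists in the direct comparison. That scaling moved epithelial genes with YAP siRNA (0.29) and stress response genes in the direct comparison (-0.0478) outside the random range. The 5 FPKM filter brought inside it the Hippo list (-0.18 IRF3 siRNA, -0.0819 YAP siRNA), mitosis (-0.0302), mesenchymal genes (-0.0808) and cholesterol synthesis (-0.0551) with IRF3 siRNA, ribosomal proteins with YAP siRNA (0.18) and growth factors (-0.17, -0.16). It moved outside the matrix list in the direct comparison (-0.0828), cholesterol synthesis with YAP siRNA (-0.0590) and apoptosis genes with IRF3 siRNA (0.26). A pseudocount of 0.1 brought inside the Hippo list (-0.24) and stress response genes (-0.0345) with YAP siRNA. Matching on length and GC content brought inside, with YAP siRNA, the Hippo list (-0.19), actin and SRF targets (-0.0791), mesenchymal genes (-0.14) and stress response genes (-0.0327), and with IRF3 siRNA mitosis (-0.13), fibroblast genes (-0.23) and cholesterol synthesis (-0.0933). It moved outside the range mitosis in the direct comparison (0.0189), gastric genes (-0.28) and ribosomal proteins (0.19) with IRF3 siRNA, and hypoxia and glycolysis with YAP siRNA (0.13). The causes were not tested. Centring changed no list's call.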

Other observations

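The test of siRNA seed matches was chosen after the direct comparison had been seen.

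Several mesenchymal, matrix and fibroblast genes were abundant in these cells and epithelial genes scarce. In the control library VIM stood at 511 FPKM, and COL3A1 and COL1A1, of the matrix and fibroblast lists, at 561 and 266. There CDH1 stood at 0.030, EPCAM at 0.084 and KRT18 at 0.076. Of 30 epithelial genes 25 had a mean below 1 FPKM, against 9 of 25 mesenchymal and 5 of 15 fibroblast genes. These genes were singled out after their values were seen, and whether cells of another type were present was not tested. Interferon-stimulated genes were mostly low too, 33 of 52 having a mean below 1 FPKM, with ISG15 at 8.42 in the control, 8.50 with IRF3 siRNA and 8.26 with YAP siRNA. The chemokine gene CXCL8 had no counts in the control or IRF3 siRNA library and 2 with YAP siRNA. ISG15 and CXCL8 were likewise named outside the rule.

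Genes that differed between both knockdown libraries might be off-targets of 1 siRNA, which would share a 7-base seed match in their 3' UTRs. Among 8102 genes and words carried by at least 100 of them, the largest absolute z was 3.87, and 63 of 100 shuffles gave one as large. A word planted in 500 genes with a shift of 0.2 gave a z of 22.3, so a broad effect of that size would have been seen, but smaller ones stay open (largest upper bound of a mean shift 0.088).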
